A study of Arabidopsis thaliana with 3 samples.

How the data were processed

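Whole aerial parts of Arabidopsis thaliana Col-0, the reference accession, were profiled on Affymetrix ATH1 arrays, which measure each gene with a set of short probes. There were 3 arrays, 1 in each of 3 groups. Per the labels, plants were grown at 20 °C in a cycle of 9 h light and 15 h dark and then held at 4 °C for 11 days. The cold-acclimated array came from plants collected at hour 5 of the light period. The other plants were frozen for 20 h from the end of a light period, at a temperature that the labels print as 6.0 °C without a sign, after which they recovered at 20 °C without light for 3 h or 24 h. Whether plants were lit during freezing is not given in the sources used here. Counting through the schedule, the 3 h array fell at hour 8 of the 24 h cycle and both the 24 h array and the control at hour 5.

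The deposited values are linear signal intensities per probe set, made by the authors with MAS5 per the submitters' processing notes, which give no version or settings. Each array already had a 2% trimmed mean near 100 over its 22810 probe sets (100.0 on each), so the rescaling applied here left the values almost as deposited. Detection calls were not used here. The depth of an array is not a count of molecules, and the number of arrays limits the precision.

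From these values each array was multiplied to a common 2% trimmed mean, and signals below a floor were set to it. The floor was the 30th percentile of all Arabidopsis signals, 16.1 on the scaled signal. Of the 22746 Arabidopsis probe sets, 69.6 to 70.5% per array lay at or above it. A log2 ratio was taken for each pair of arrays, and probe sets past a 2-fold difference were counted. With 1 array per group there is no replicate check, so no test was run and no p-value is given; a ratio describes 2 arrays, and not the spread between plants. The error that the arrays give is the difference between 2 probe sets of one gene, which covers probe and hybridization error. Its SD, divided by the square root of 2, was 0.33 for 3 h against the control, 0.40 for 24 h against the control and 0.36 for 24 h against 3 h, over 76 genes each.

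Gene names came from the platform's annotation, with symbols updated through the RefSeq table of assembly TAIR10.1. That annotation gave 1 gene for 13513 probe sets, several for 503, and none for 8730 of the Arabidopsis probe sets, which are unnamed here. Many well-studied genes are among the unnamed, SFR2 and the CBF factors included, and these are not analysed here. No coordinates are printed, because the values name no build.

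Lists of genes were written before the data were examined (27 lists, 598 places, of which 163 were on the annotation). Members of the plastid-encoded (69 places) and mitochondrion-encoded (16 places) lists were not written out then. They came from the annotation itself, so all of these places are on it. Another 22 lists were added after seeing which genes the annotation names and before any ratio was computed. Members were matched by locus code, and 5 were left out because the reference gave the code another name. The brightest probe set stood for a gene, and a member below the floor on both arrays counted as not measured. A list with at least 3 measured members is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched in 20 bins of mean signal, as a description of these arrays. The genes named were chosen by a rule fixed beforehand, whose step for members of the fixed lists was applied to the added lists as well. It took, for each comparison, the 12 highest and 12 lowest ratios among probe sets of 1 gene, without cross-hybridizing ones, above the floor on both arrays and with the brighter signal at or above the median of all signals (41.7); the 5 brightest with the other array at the floor, as bounds; and the 4 list members of largest ratio.

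Alternatives were the values as deposited, scaling to a common median, quantile normalization, a loess correction per pair, scaling to a list of reference genes, floors at the 15th and 45th percentile, a pseudocount in place of the floor, and leaving out cross-hybridizing probe sets. Scaling to the bacterial hybridization controls was added after seeing the data. The counting and list functions were tested on simulated data made from the 22810 probe sets, with 200 changed, for 3 h against the control. The 200 were drawn only from probe sets far above the floor on all 3 arrays, so the rates of finding them do not hold for dim ones. The unchanged ones included probe sets held at the floor, which cannot pass. With an SD of 0.25 log2 units per array, changes of 1.5 log2 units were found past 2-fold in 98% of 50 raised and 96% of 50 lowered probe sets, changes of 3 in 100%, and 0.33% of 22546 unchanged ones passed. Of 200 unshifted lists, 2% lay outside the central 95% of random lists, and 8% did with an SD of 0.2. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.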

Results

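The series followed gene expression in cold-acclimated Arabidopsis plants as they recovered from freezing. A cold-acclimated array served as the control, and 1 array each was made after 3 h and 24 h of recovery at 20 °C in the dark. Cold acclimation is the rise in freezing tolerance that follows days at low, non-freezing temperature. The control differed from both recovery arrays in freezing, in temperature and in light at harvest, and with 1 array per group these differences cannot be separated. The median signal was 42.6 on the cold-acclimated array, 39.5 at 3 h and 42.8 at 24 h. The bacterial hybridization controls, added in fixed amounts before hybridization, were 1.70-fold higher at 3 h and 1.43-fold higher at 24 h than on the control array after scaling. Scaling to these controls instead lowered the log2 ratios against the control by 0.76 at 3 h and 0.52 at 24 h, except where the floor limits them.

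The comparison of the 3 h array with the control asked which transcripts differ early in recovery. Single genes for calcium sensors, a zinc-finger repressor and ubiquitin ligases were at least 4-fold higher at 3 h. In the added lists of such families, 3 of 7 calmodulin-like genes and 4 of 8 U-box ubiquitin ligases were at least 2-fold higher, with medians of 0.32 and 0.84. With scaling to the hybridization controls these medians were -0.44 and 0.07. The calmodulin-like protein CML38 had a signal of 34.1 on the control and 1507 at 3 h (log2 ratio 5.46), and CML37 went from 35.7 to 477.0. The zinc-finger repressor STZ was at 162.6 and 1273 (2.97). Among the U-box ubiquitin ligases PUB19 was at 105.2 and 965 (3.20) and PUB23 at 26.9 and 120.4 (2.16). PDF1.2, a defensin used as a marker of jasmonate and ethylene signalling, was at 719 and 3934 (2.45).

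Among the lists, endoplasmic reticulum folding had 2 of 3 measured members at least 2-fold higher and a median log2 ratio of 1.44, at percentile 99.1 of the random lists, or 0.67 with scaling to the hybridization controls. BZIP28 and BZIP60, membrane-bound factors of the unfolded protein response, were at 107.3 and 454 on the control and at 441 and 1228 at 3 h. The only other measured member, ATERDJ3B, lay within 2-fold, at 459.4 and 562.4. Of the 18 genes written for this list, 3 were on the annotation, so the median says little about folding genes at large. Stress transcription factors and calcium sensors had 2 of 4 members at least 2-fold higher and a median of 0.74 (percentile 98.7), which became -0.02 with scaling to the hybridization controls. The 4 measured were STZ, WRKY22, WRKY6 and WRKY53, so no calcium sensor entered this median. WRKY22 was at 25.4 and 72.7, whereas WRKY6 (91.4 and 83.6) and WRKY53 (148.9 and 145.6) lay within 2-fold. The cold regulon, the genes raised during cold acclimation, had 1 of 4 members at least 2-fold higher and a median of 0.50 (percentile 97.48), or -0.26 with scaling to the hybridization controls. Its dehydrin COR47 was at 1288 and 3852, and LTI30 at 2846 and 4961, while COR15A (3969 and 4581) and COR15B (2370 and 2538) lay within 2-fold. Single measured members of other lists were SAG101 of salicylate defence (59.0 and 167.2) and the late embryogenesis abundant protein LEA4-5 of dehydration (31.5 and 209.8).

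The phenylpropanoid and anthocyanin list had 2 of 5 members at least 2-fold lower at 3 h, with a median of -0.93 (percentile 0.29). AT4G14090 was at 103.4 and 34.8, and the anthocyanin malonyltransferase AT5MAT at 60.8 and 27.8. All 10 measured photosynthesis genes and all 9 dark-induced and starvation genes lay within 2-fold, with medians of -0.21 and 0.03, or -0.97 and -0.73 with scaling to the hybridization controls. Oxidative stress and detoxification had 1 of 3 members past 2-fold, the alternative NADH dehydrogenase NDB2 (303.4 and 662), and heat shock proteins and factors had 1 of 4, AT5G37670, at 46.0 and 20.0; their medians were 0.11, or -0.65 with scaling to the hybridization controls, and -0.10.

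By ratio alone, AT1G15010 was highest at 3 h, at 39.5 and 2372 (5.91). The other 11 of the 12 highest ratios ranged down to 3.83, among them AT2G27080 (32.7 and 1107), AT1G05340 (31.9 and 940), AT4G35985 (35.8 and 1016) and the expansin-like EXLA1 (94.5 and 1550). AT2G22880, at the floor on the control, was at least 32.1-fold higher, and UGT76E12, a glycosyltransferase, at least 14.4-fold. The lowest ratios were AT3G15570 at 182.5 and 22.8, AT3G44450 at 560 and 72.0 (-2.96) and AT5G44680 at 134.1 and 17.39 (-2.95). The transcription factor gene AT5G61590 was at 331.7 and 53.9 (-2.62).

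In all, 1024 probe sets were at least 2-fold higher and 663 at least 2-fold lower at 3 h than on the control, of 16769 measured on either array. At least 4-fold differences numbered 324 higher and 32 lower. Of the 2-fold differences 60.7% were higher; the share was 73.9% after the loess correction and 6.54% with scaling to the hybridization controls, where 439 were higher and 6274 lower. In 20 simulations with the noise between probe sets as the only difference, 42.5 probe sets on average were higher and 41.2 lower. This noise came from probe sets above the floor on both arrays and was given to dim ones too. It leaves out the spread between plants and any larger error of dim probe sets. Of the 2-fold differences at 3 h, 150 of the higher and 100 of the lower had 1 array at the floor.

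**Figure D1:**
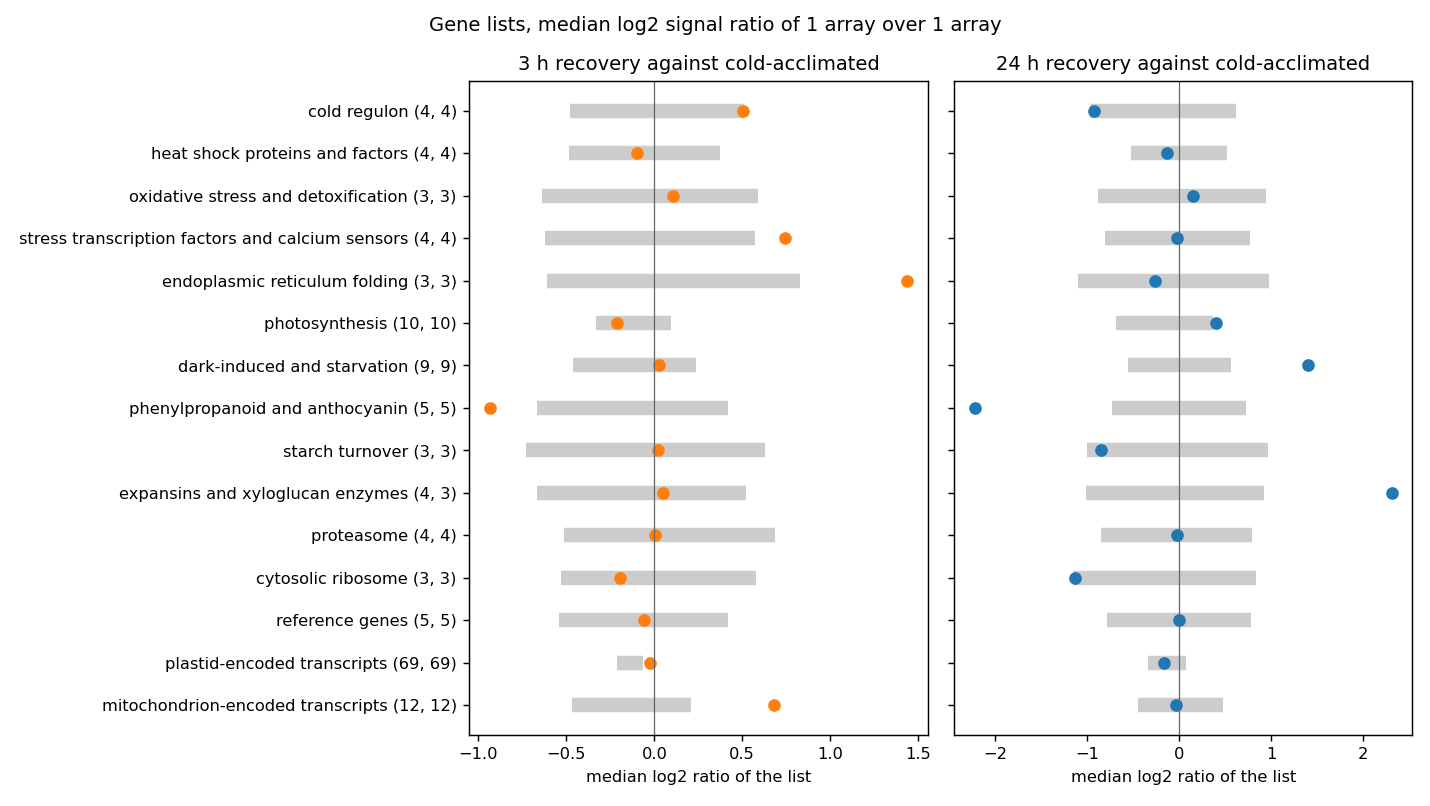
Median log2 ratio (x axis, log2 of 1 array's signal over the other's) of each list fixed beforehand that had at least 3 measured members in both comparisons, with the numbers measured at 3 h and at 24 h in brackets. Points are list medians for 3 h (left) and 24 h (right) against the cold-acclimated array, and grey bars span the central 95% of 10000 random lists matched on signal; the dark-induced and starvation point lies at 0.03 on the left and 1.401 on the right.

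The comparison of the 24 h array with the control asked which transcripts differ after a day of recovery. Genes of starvation and amino acid breakdown had higher signals, and genes of anthocyanin synthesis and the ribosome had lower ones. The dark-induced and starvation list had 7 of 9 members at least 2-fold higher and a median of 1.401 (95% order-statistic interval over its genes 0.72 to 2.85, percentile 100). With scaling to the hybridization controls this median was 0.88. AKINBETA1, a subunit of the energy-sensing kinase SnRK1, was at 54.9 and 431.5. The autophagy protein ATG8E was at 81.7 and 589. IVD and MCCA, enzymes of leucine breakdown, were at 36.0 and 214.1 and at 35.7 and 189.1.

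All 5 measured phenylpropanoid and anthocyanin genes were at least 2-fold lower at 24 h, with a median of -2.22 (percentile 0), or -1.64 with the floor at the 45th percentile. UGT78D2, a flavonoid glucosyltransferase, was at 187.4 and 27.3, and DFR, dihydroflavonol reductase, at 112.8 and 24.2. The cold regulon had 2 of 4 members at least 2-fold lower and a median of -0.93 (percentile 3.2): COR15B was at 2370 and 545 and COR15A at 3969 and 1780, while COR47 was at 1288 and 1426. Endoplasmic reticulum folding (median -0.26) and stress transcription factors (median -0.03) each had no member past 2-fold. STZ was at 162.6 and 162.1.

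The cytosolic ribosome list had 2 of 3 members at least 2-fold lower and a median of -1.13 (percentile 2.7); AT5G02870 was at 2602 and 1087. Among the added lists, 42 of 105 ribosomal protein genes were at least 2-fold lower and 0 higher, with a median of -0.89 (interval -1.01 to -0.79; percentile 0). Ribosome biogenesis had 16 of 17 genes at least 2-fold lower, among them AT1G52930 at 374.5 and 60.4. Its median was -1.72 (interval -1.99 to -1.42, percentile 0), or -1.54 with the floor at the 45th percentile and -1.42 with a pseudocount. On the same array the control probe set for 25S ribosomal RNA was 5.42-fold higher than on the cold-acclimated array, and that for 5S ribosomal RNA was lower, at 75.6 on the control and 7.98, below the floor, at 24 h.

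Photosynthesis genes had a median of 0.40 (interval -0.77 to 0.70; percentile 98.1), or -0.13 with scaling to the hybridization controls, and went both ways: the light-harvesting gene LHCB4.2 was at 1965 and 4153, and its relative LHCB4.3 at 500.7 and 73.9. The added list of the Calvin cycle, photosystems and chlorophyll synthesis had 0 of 8 higher and 1 lower, with a median of 0.04 (percentile 73.0), or -0.48 with that scaling. Expansins and xyloglucan enzymes had 2 of 3 members at least 2-fold higher and a median of 2.31 (percentile 100), or 1.27 with the floor at the 45th percentile and 1.59 with a pseudocount, with EXPA8 at 36.1 and 280.4 and XTH33 at 15.8, below the floor, and 80.01. The larger added list of the same families had 4 of 17 at least 2-fold higher and 1 lower, with a median of 0.06 (percentile 55.9), or -0.30 with scaling to the hybridization controls. Starch turnover had 1 of 3 members past 2-fold in each direction, the amylase AMY1 (33.3 and 125.7) and APL3, a subunit of ADP-glucose pyrophosphorylase (154.8 and 58.6). Both measured low oxygen and fermentation genes were at least 2-fold lower, PDC2 at 458.5 and 218.3 and AT4G17260 at 233.5 and 104.2. Of 2 light signalling genes HYH was lower (112.4 and 23.49) and PORB lay within 2-fold (2168 and 2457). Senescence and chlorophyll breakdown had 1 of 3 members at least 2-fold higher, SAG29, below the floor on the control (10.6) and at 82.9 at 24 h, and a median of -0.06. The clock gene GI was at 659 and 277.5, LEA4-5 at 31.5 and 122.1, and SAG101 at 59.0 and 63.7.

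The highest ratios at 24 h were those of AT4G27450 at 32.8 and 1174 (5.16) and the defensin-like PDF1.4 at 28.5 and 989 (5.12), followed by AT2G20670 (38.0 and 956) and AT2G05540 (37.0 and 813). AT1G15010, highest at 3 h, was at 528 (3.74). JRG21 was at least 25.9-fold higher than on the control, where it lay at the floor. The lowest ratios were AT3G44450 at 560 and 35.7 (-3.97), AT1G31690 (-3.89), at 258.2 on the control, and the plastid gene ndhF at 260.9 and 19.0 (-3.78). The sucrose-phosphate synthase ATSPS4F was at 254.1 and 23.8 (-3.42), the sucrose transporter SWEET13 at 349.2 and 49.9 (-2.81) and the glutathione transferase GSTU20 at 1143 and 173.3 (-2.72). CHIL, a chalcone isomerase-like protein, was at least 8.98-fold lower, at the floor at 24 h.

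In all, 1453 probe sets were at least 2-fold higher and 1437 at least 2-fold lower at 24 h than on the control, of 16965 measured. At least 4-fold differences numbered 291 and 147. Of the 2-fold differences 50.3% were higher, 48.6% with quantile normalization, 49.8% with median scaling and 14.8% with scaling to the hybridization controls, where 672 were higher and 3867 lower.

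**Figure D2:**
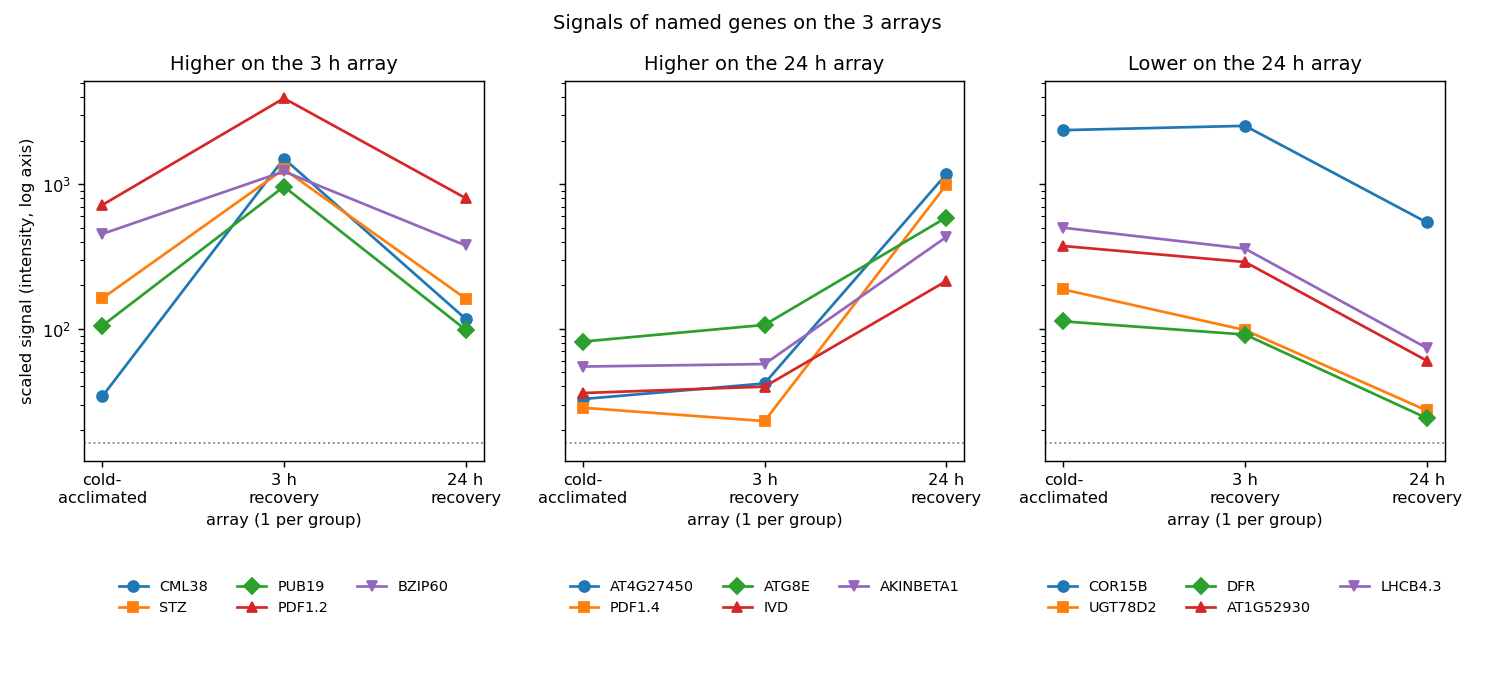
Scaled signal (y axis, intensity on a log axis) of 15 named genes on the cold-acclimated, 3 h and 24 h arrays, 1 array per group, so points have no error bar; the dotted line is the floor of 16.1. CML38 runs from 34.1 to 1507 and 117.4, AT4G27450 from 32.8 to 42.0 and 1174, and COR15B from 2370 to 2538 and 545.

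The comparison of the 24 h with the 3 h array, both from darkness at 20 °C, asked how expression differs between early and late recovery. The last light period before freezing had ended 23 h before the 3 h harvest and 44 h before the 24 h harvest. Longer darkness and the hour of the cycle (8 and 5) therefore cannot be told apart from recovery time. All 4 cold regulon genes were at least 2-fold lower at 24 h than at 3 h, with a median of -1.46 (percentile 0.10), as were all 3 endoplasmic reticulum folding genes, with a median of -1.45 (percentile 1.15). Dark-induced and starvation genes were at least 2-fold higher in 8 of 9 cases, with a median of 1.96 (percentile 100). Phenylpropanoid and anthocyanin genes were at least 2-fold lower in 4 of 5, with a median of -1.13 (percentile 0.31), or -1.85 with the floor at the 15th percentile. STZ was at 1273 and 162.1 and PDF1.2 at 3934 and 803. The lowest ratios were AT4G35985 (1016 and 58.9), AT2G17660 (297.7 and 17.5) and AT1G51090 (1010 and 60.6). AT2G20670, at the floor at 3 h (4.38 and 956), was at least 59.2-fold higher. Among probe sets above the floor on both arrays, the highest ratios were those of PDF1.4 (23.1 and 989), AT5G39520 (21.4 and 639) and AT4G27450 (42.0 and 1174). In all 1813 probe sets were at least 2-fold higher and 1471 lower, of 16968 measured. Of these 55.2% were higher. The share was 46.1% with median scaling (1522 higher and 1783 lower), 49.4% with reference gene scaling, 49.6% with quantile normalization, 49.8% after loess and 72.4% with scaling to the hybridization controls, so which direction held the majority depended on the scaling.

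The 5 reference genes, chosen for stable expression, had medians of -0.06 at 3 h and -0.01 at 24 h against the control. PEX4 was at 217.3, 229.3 and 214.1 on the control, 3 h and 24 h arrays. Proteasome genes had medians of 0.00 and -0.02, with 0 of 4 past 2-fold at either time. Among the scalings, these near-zero medians turned sign in part, and with that to the hybridization controls they were -0.82 and -0.53 for reference genes and -0.76 and -0.54 for the proteasome. The 69 plastid-encoded transcripts had medians of -0.02 at 3 h and -0.17 at 24 h (percentiles 99.7 and 41.0). At least 2-fold lower were 8 and 11, and 1 at each time was at least 2-fold higher. The 3 h median, though near 0, thus lay above the central range of the random lists (-0.21 to -0.06). Its interval over the genes was -0.23 to 0.09. The 3 h median was above 0 with median scaling (0.085), reference gene scaling (0.094) and loess (0.059). The plastid gene rbcL was at 2430, 1255 and 464. The 12 mitochondrion-encoded transcripts had a median of 0.68 at 3 h (percentile 99.98, interval -0.99 to 0.96), which was -0.13 with scaling to the hybridization controls, 0.13 with the floor at the 45th percentile and 0.50 with a pseudocount. Their median at 24 h was -0.04, or -1.06 with the floor at the 45th percentile. The cell division gene AUR1 was at 91.6, 65.2 and 51.1. The lists of ethylene response, freezing tolerance loci and membrane lipids, flower organ markers, and vascular and guard cell markers each had 0 measured members.

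Across 17379 probe sets, which are not independent replicates, the log2 ratios at 3 h and 24 h against the same control array had a Pearson correlation of 0.32 and a covariance of 0.17. Noise alone with the shared control gave 0.50 and 0.06, so the covariance difference was 0.11. The limits of this noise given above for the counts hold here too. At least 2-fold higher at both times were 281 probe sets and lower at both 181, where independent lists would share 85.6 and 54.8 and noise alone 4.0 and 4.1; part of the excess may come from the shared control array. Of the 1024 probe sets higher at 3 h, 620 (60.5%) were at least 2-fold lower again at 24 h than at 3 h. Of the 663 lower at 3 h, 315 (47.5%) were at least 2-fold higher again. In both patterns the 2 differences share the 3 h array, so an error of that array alone would give both. A further 1104 were higher and 1231 lower at 24 h while within 2-fold of the control at 3 h.

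**Figure D3:**
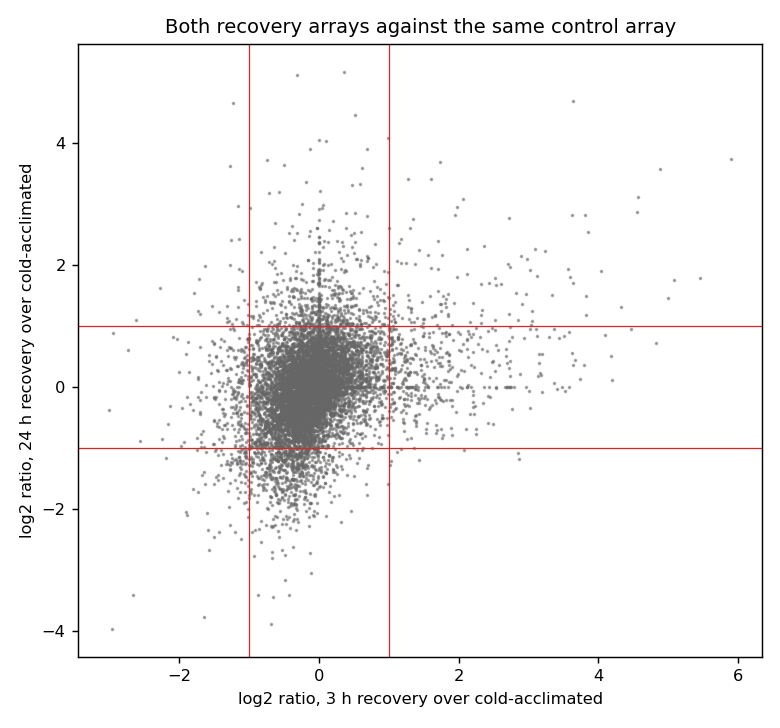
Log2 ratio at 24 h (y axis) against that at 3 h (x axis), both over the same cold-acclimated array, for the 9746 probe sets of 1 gene measured on any array; each point is a probe set and red lines mark 2-fold. Over all 17379 measured probe sets the correlation was 0.32.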

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

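The tests of the 25S pattern, of ribosome biogenesis and of the hour of the day were chosen after results that bear on them had been computed; the test of the scaling of the 3 h array was set out before its result was seen, and its interval and the count set against noise were added after. A rule for samples far from their group could not be applied, as each group held 1 array.

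Some control probe sets that the comparisons do not use stood above their level on the cold-acclimated array. The probe set for 25S ribosomal RNA was 5.42-fold higher at 24 h, at 238.3, 444.3 and 1292 on the control, 3 h and 24 h arrays, whereas that for 5S ribosomal RNA was at 75.6, 65.1 and 7.98, the last below the floor. RNA degradation would raise the signal near the 3' end of the actin, GAPDH and ubiquitin controls over that near the 5' end, but the median fold of their 6 ratios at 24 h was 0.81 (range 0.63 to 1.16). Array scaling would raise the hybridization controls as much, and their mean fold was 1.43. Ribosomal RNA carried into the labelled material may differ between the arrays, and a biological change stays open; neither was tested.

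The hybridization controls were 1.70-fold higher at 3 h and 1.43-fold higher at 24 h. A ubiquitin control probe set for the 5' end was 2.08-fold higher at 3 h, and another for the middle of the transcript 2.15-fold higher at 24 h.

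Some probe sets lay on opposite sides of the control at the 2 times, and the difference was not tested. At least 2-fold higher at 3 h and at least 2-fold lower at 24 h were 25, and 68 went the other way, against 84.7 and 55.4 for independent lists and 0 each with noise alone. Both ratios share the control array, which by itself makes opposite sides less frequent. AT5G61590 was among the latter, at 331.7, 53.9 and 705.6.

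Ribosome biogenesis genes were lower at 24 h than on the control. Array scaling, which moves all probe sets alike, and signal-dependent bias are argued against as the whole cause by the position of the list median below all 10000 random lists matched on signal. The median was -1.68 or lower under every scaling tried, the loess correction (-1.68) included. These scalings raised the median ratio of all probe sets at 24 h by at most 0.04, too little to undo the list median. Its range under them therefore adds no support beyond its position among the random lists. Darkness instead of freezing cannot be told apart, since no array came from unfrozen plants in darkness. The dark-induced and starvation list had a median of 1.401 in the same comparison. The difference in temperature between control and recovery arrays cannot be told apart either, since no array came from unfrozen plants returned to warmth. The effect of freezing likewise stays open, untested.

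The 620 probe sets higher at 3 h and lower again at 24 h could reflect the scaling of the 3 h array. With scaling to the hybridization controls, the scaling that lowers the 3 h array most, 53.4% kept both 2-fold differences (95% exact binomial interval 49.4 to 57.4%, with probe sets taken as independent). These 331 probe sets argue against scaling of up to that size as the whole cause. At most 5 showed the pattern with noise alone. Those simulations kept the main scaling, and their noise came from probe sets above the floor and left out the spread between plants. The count of 5 is therefore not a like comparison. The share of 53.4% lies above the bound of 50% set beforehand, though that bound lies within the interval. The interval covers no error between arrays or plants, and both differences share the 3 h array. How many of the other 289 reflect scaling cannot be told apart. The remaining scalings kept 97.4 to 100% but raise the 3 h array or leave it as it was. The hour of the day cycle cannot be told apart from recovery time, since the 3 h array was the only one from hour 8. A passing response to thawing, or to the return to warmth, stays open, untested.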

How the results depend on the processing

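No paired analysis was possible because each group held 1 array and the groups share only 1 replicate number. Scaling to the hybridization controls was chosen after seeing the data; the other alternatives were fixed before the data were examined. Of 60 values of the 6 counts under alternatives, 48 were within 1.5 times the main count. With the floor at the 15th percentile, 1659 were higher and 1446 lower at 3 h, 2234 higher and 2195 lower at 24 h, and 2258 lower at 24 h than at 3 h; this floor admits dimmer signals. The 663 lower at 3 h became 434 after loess, 403 with the floor at the 45th percentile and 392 with a pseudocount. Scaling to the hybridization controls shifted the median ratio of all probe sets by -0.71 at 3 h, -0.48 at 24 h and 0.22 between them, and gave 439 higher and 6274 lower at 3 h and 672 higher and 3867 lower at 24 h. For 3 h against the control, the shift was 0.10 with median scaling, 0.11 with reference genes and 0.14 with loess; for 24 h against 3 h it was -0.11 with median scaling. The correlation of 0.32 was 0.35 with the floor at the 15th percentile and 0.38 with hybridization control scaling. Under that scaling the list medians at 3 h were -0.97 for photosynthesis, -0.73 for dark-induced and starvation genes, -0.79 for plastid-encoded and -0.13 for mitochondrion-encoded transcripts, -0.022 for stress transcription factors, -0.44 for calmodulin-like proteins and -0.026 for auxin response, and at 24 h -0.125 for photosynthesis; plastid-encoded transcripts were at -0.69 at 24 h and 0.15 at 24 h against 3 h. Plastid-encoded transcripts were at 0.094 at 3 h with reference gene scaling, 0.085 with median scaling and 0.059 after loess, and between the recovery arrays at -0.21 with median scaling and 0.047 with loess. Beyond the shifts these scalings add by construction, the cause was not tested. Of 1093 list medians under alternatives, 1015 moved less than their spread, 70 moved more and 8 changed sign from a median outside the central 95% of random lists. Of 7831 ratios of named genes, 6935 moved less than the noise between probe sets and 896 moved more. Signals near the floor limit the low ratios, since 27 bacterial control probe sets with no target had medians of 1.4 to 1.8 and reached 18.6.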

Other observations

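Further families, added after the annotation was seen, stood apart in these arrays. Autophagy genes had 7 of 10 members at least 2-fold higher at 24 h than on the control. Their median log2 ratio was 1.35 (percentile 100), or 0.83 with scaling to the hybridization controls. ATG8F was at 600 and 1816, and ATG8H below the floor at 14.8 and at 123.9. Their member ATG8E is also in the fixed starvation list. At 3 h the median of the autophagy genes was 0.03, or -0.73 with scaling to the hybridization controls. Branched-chain amino acid breakdown and starvation genes, some of which the fixed starvation list also holds, had 9 of 12 at least 2-fold higher and a median of 1.82 (percentile 100); AT4G33150, which encodes the enzyme of lysine breakdown, was at 43.5, 26.4 and 394.5 on the control, 3 h and 24 h arrays. RNA polymerase subunits had 5 of 11 at least 2-fold lower at 24 h and a median of -0.94 (percentile 0.005), among them NRPA1 at 81.5 and 29.1. U-box ubiquitin ligases had 4 of 8 at least 2-fold higher at 3 h and a median of 0.84 (interval -0.35 to 3.20; percentile 99.98), which was 0.07 with scaling to the hybridization controls, and a median of -0.09 at 24 h.

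Calmodulin-like genes had 4 of 7 at least 2-fold higher at 24 h and a median of 1.06 (interval -0.40 to 1.78; percentile 99.9), or 0.13 with the floor at the 45th percentile, with CML41 at 65.0, 33.1 and 145.5. Auxin response genes had a median of 0.39 at 3 h (percentile 99.9), with 0 of 7 past 2-fold, and of 0.69 at 24 h (percentile 99.6), with 1 of 6 past 2-fold. With scaling to the hybridization controls these medians were -0.03 and 0.16. The 3 h median was 0.60 with the floor at the 15th percentile, and none was available with the floor at the 45th. UDP-glycosyltransferases went both ways at 3 h, 7 of 33 at least 2-fold higher and 2 lower. Their median was -0.19 (percentile 23.7), so as a list they did not stand apart. UGT76E11 was at 60.5 and 399.5 and UGT78D1 at 149.8 and 55.5. The remaining added lists with at least 3 measured members had medians between -0.39 and 0.22 at 24 h against the control, those above 0 falling below it with scaling to the hybridization controls. That range does not cover 24 h against 3 h. There IQ-domain proteins, for example, had 3 of 10 at least 2-fold higher and 2 lower, with a median of 0.71 (percentile 99.2).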
